A study of Rattus norvegicus with 12 samples.

How the data were processed

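Circular DNA from the back skin of wild-type Sprague Dawley rats was sequenced by Circle-seq, which digests linear DNA and sequences the circles that remain. The labels give 12 libraries in 3 groups of 4: untreated control skin, skin taken on day 7 after 2 weekly fractions of 5 Gy of electron beam radiation (5 Gy x2), and skin taken on day 7 after 4 such fractions (5 Gy x4). Per the labels, circular DNA was enriched on plasmid columns, treated with exonuclease, purified on beads and made into libraries with a transposase kit from 50 ng of input. The labels do not say when control skin was taken, and the higher total dose also means a later sampling time, so dose and time cannot be separated in these groups. The labels do not say whether the 4 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

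The authors deposited 1 table per library and 2 annotation tables for the whole series. Per the labels and file headers, the values of each library table are counts: whole-number supporting reads (split reads plus discordant read pairs) for each circle of 1 list common to all libraries, with no normalization. The submitters' processing notes name BWA, Picard and bedtools without versions, and the genome build rn6; the circle caller and the rule by which circles of different libraries were merged are not given in the sources used here. The deposited annotation tables give each circle's position, length, supporting reads, overlap with genes and a label of hconf, conf or lconf, which the tables do not define. They also list the calls of single libraries: 6 of these columns (3 in each of the 2 tables: split reads, discordant pairs and the caller's score) were not used here, and the mean depth was used for the mitochondrial circle alone. In 227 of the 228510 entries the library counts summed to less than the total in the table, and 5 list cells of unequal length were dropped. Starts are counted from 0 in the tables and from 1 here.

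The list holds 228353 extrachromosomal circular DNAs (eccDNA) and 157 larger circles listed apart as ecDNA. A circle was counted as present in a library when it had at least 1 supporting read there. Supporting reads per library ran from 35525 to 404815. The total sequencing depth is unknown, so the number of circles as listed was taken as the main value, and numbers drawn down to 32211 supporting reads per library, or divided by supporting reads or by the depth over the mitochondrial circle, were taken as alternatives.

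For each library the number of eccDNA, their median length, the share under 1000 bp, the share overlapping an exon or intron (genic share) and the number of ecDNA were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The 3 pairs of groups were compared with a two-sided exact permutation test of the difference in means over all 70 splits of 8 libraries, with Benjamini-Hochberg adjustment over the 15 tests of these 5 measures. The smallest p that 4 libraries against 4 allow is 0.0286, which cannot pass an adjusted threshold of 0.05 unless most tests reach it. A second family of 69 such tests covers measures added after the data were seen, among them the share of circles of 330 to under 420 bp, the number in 6 length classes, exon, intron and flank shares and the mitochondrial circle. The share of circles on each of 22 chromosomes was tested in the same way and adjusted over chromosomes. Sharing between libraries was the percent of one library's circles that overlapped a circle of another by at least 50% of both (bedtools 2.31.1), compared within and between groups by a permutation test with 100000 resamples.

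The number of eccDNA annotated to the exons or introns of each of 14890 genes was tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F test) in 1 fit of all 12 libraries with group as the only term, at an adjusted p of 0.05. The libraries' genic circles are few per gene, so the filter left 15 genes. The fit measures a gene's share of circles relative to the other tested genes, not its absolute number. The named genes were those past the threshold whose 4 libraries of one group all lay above the 4 of the other, at most 12 in each direction, or the 10 lowest p values where fewer than 5 genes passed; up to 4 members of each gene list with the lowest p; the 10 circles found in most libraries; and the 5 longest and 5 best supported ecDNA. The design, this rule and 15 gene lists were fixed before the data were examined: DNA damage and p53 response, DNA repair, extracellular matrix and fibrosis, epidermal keratinocyte, hair follicle and sebaceous gland, inflammation, immune cell, skeletal muscle, adipocyte, endothelium and pericyte, Schwann cell and melanocyte, oncogene and growth factor receptor, oxidative stress, apoptosis, and long neuronal genes as a control for gene length. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Because the filter left 1 list with at least 2 members, the lists were also tested on all genes with a circle and library size alone, a choice made after the data were seen. Camera compares a list with the other genes, while fry, an alternative, tests its members for a change of their own.

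After the gene counts proved sparse, circles were also counted by their start in 291 windows of 10 Mb (windows of 10000000 bp), of which 286 passed the filter, with the same edgeR fit. Up to 4 windows with the largest rise and 4 with the largest fall among those past the threshold with groups apart were named. To hold length fixed, the share of circles in gene-dense windows was computed within 20 length bins and weighted by the mean mix of the 12 libraries, a test added after the data were seen. On simulated counts with the same library sizes, the window fit recovered 66.7% of 1.5-fold and 100% of 2-fold changes with 2 false calls among 226 unchanged windows. The filtered gene fit recovered 75% of the 12 tested genes changed 4-fold and 0 of the 2 changed 2-fold, with 2 false calls among 8 unchanged genes, and without a filter library size alone recovered 5% of 100 genes changed 4-fold and 0 of 100 changed 2-fold, and TMM 21% and 7%, with 0 false calls each. Alternatives covered the filter, the normalization, the tool (DESeq2 1.42.0, limma-voom), replicate number as a block, the support and length of circles, and leaving out each library. GC content was not corrected for, since no genome sequence was used here. Figures were drawn with matplotlib 3.10.9.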

Results

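The data set lists circular DNA in 12 libraries of rat back skin, 4 from untreated skin (control), 4 from skin given 2 weekly fractions of 5 Gy of electrons (5 Gy x2) and 4 given 4 such fractions (5 Gy x4). The series title sets out to compare circular DNA between these fractionated doses. Across the libraries, 243817 calls fell on 228353 listed eccDNA, of which 96.1% were found in 1 library only and 10 in all 12. The listed eccDNA had a median length of 360 bp, with an upper quartile of 383 bp and a range of 8 to 99725 bp. By annotation, 137063 entries lay between genes, 73152 in introns, 10738 in exons, 3873 in the 2 kb upstream and 3527 in the 2 kb downstream of a gene. In control libraries the supporting reads came to 35525, 119480, 197061 and 110227 for replicates 1 to 4. The 5 Gy x2 libraries held 404815, 98352, 281874 and 52159 supporting reads, and the 5 Gy x4 libraries 186977, 324186, 181736 and 321582. Supporting reads are amplified reads without molecular identifiers, so they are not independent molecules.

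On average, irradiated skin libraries held more circles than control skin libraries. Control libraries listed 7057.5 ± 3360 eccDNA (mean ± SD, n = 4), 5 Gy x2 libraries 20383 ± 10319 and 5 Gy x4 libraries 33273 ± 14082. The 5 Gy x4 mean was 4.71-fold the control mean, and each of its 4 libraries (20124 to 46163) exceeded each control library (3601 to 10389). Its two-sided exact permutation p was 0.0286, the smallest that 4 libraries against 4 allow, with an adjusted p of 0.0857 over 15 tests. Without any 1 control library the groups still lay apart, with an exact p of 0.0571 or 0.0857 and a fold of 4.05 to 5.59. The 5 Gy x2 mean was 2.89-fold the control mean (exact p = 0.0857, adjusted p = 0.214), with replicate 4 at 6326 circles inside the control range. Without that library the 5 Gy x2 mean was 3.55-fold the control mean (exact p = 0.0286). The 5 Gy x4 mean was 1.63-fold the 5 Gy x2 mean, which was within the spread between libraries (exact p = 0.229).

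Total sequencing depth is unknown, and 3 other scales gave smaller folds. Divided by supporting reads, the number of eccDNA was 1.88-fold the control value in 5 Gy x2 (exact p = 0.400, n = 4) and 1.85-fold in 5 Gy x4 (exact p = 0.229), and 0.984-fold between the doses (exact p = 0.971). In 5 Gy x2 this value was highest in replicate 2, which listed 28757 circles on 98352 supporting reads. With 32211 supporting reads drawn from each library, control libraries held 5714 ± 2047 circles, 5 Gy x2 libraries 12537 ± 4985 (2.19-fold, exact p = 0.0857, n = 4) and 5 Gy x4 libraries 16269 ± 3536 (2.85-fold, exact p = 0.0286). The mitochondrial genome, an abundant circle of cells, was listed as 1 entry from base 1 to base 16311. Its mean depth was 24535 ± 17838 in control, 89123 ± 43692 in 5 Gy x2 (3.63-fold, exact p = 0.0571, n = 4) and 114976 ± 21000 in 5 Gy x4 (4.69-fold, exact p = 0.0286). Without control replicate 1, the library with the highest control depth, these folds were 5.48 (exact p = 0.0571) and 7.07 (exact p = 0.0286). Divided by that depth, the number of eccDNA was 0.584-fold the control value in 5 Gy x2 (exact p = 0.171, n = 4) and 0.776-fold in 5 Gy x4 (exact p = 0.486), a turned direction at both doses (0.467 and 0.621-fold without control replicate 1, exact p = 0.0571 and 0.171). The number of circles with the label hconf was 1.91-fold the control value in 5 Gy x2 (exact p = 0.114, n = 4) and 3.28-fold in 5 Gy x4 (exact p = 0.0286).

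Circles near the length of DNA on a pair of nucleosomes made up most of the difference in number. Circles of 330 to under 420 bp were 32.2% ± 11.9 of control circles (SD, n = 4), 66.5% ± 3.98 of 5 Gy x2 circles and 67.2% ± 2.42 of 5 Gy x4 circles. Every irradiated library (60.5% to 70.3%) lay above every control library (16.1% to 44.6%), with an exact p of 0.0286 for each dose and an adjusted p of 0.110 over the 69 added tests. The 5 Gy x4 share differed from the 5 Gy x2 share by 0.713 percentage points (adjusted p = 0.880 of the exact test, n = 4). The 5 Gy x2 library with only 6326 circles held 60.5% in this class. In number, circles of 330 to under 420 bp went from 2529 ± 1800 per control library to 22581 ± 10178 in 5 Gy x4, 8.93-fold (exact p = 0.0286). Circles of 150 to under 250 bp were 3.01-fold and circles of 420 to under 1000 bp 2.57-fold the control number in 5 Gy x4 (exact p = 0.0286 each), and circles of 250 to under 330 bp 2.34-fold (exact p = 0.0571). Circles under 150 bp were at 0.714-fold (exact p = 0.143) and circles of 1000 bp or more at 1.24-fold (exact p = 0.486) of the control number. At 5 Gy x2 the 330 to under 420 bp class was 5.47-fold the control number (exact p = 0.0571), and the folds of the other 5 classes ran from 0.669 to 1.75. The length class was chosen after the length profile was seen.

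**Figure D1:**
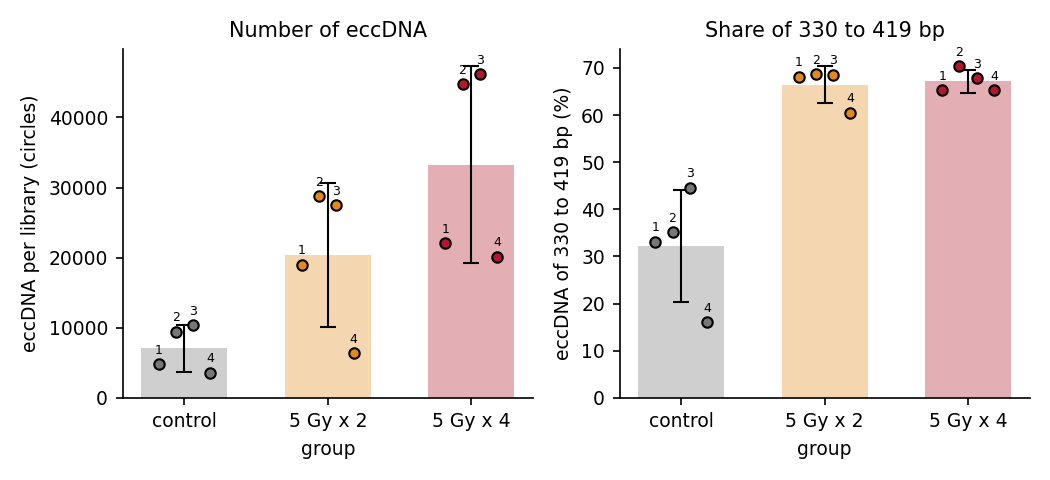
Number of eccDNA per library (left axis, circles) and share of circles of 330 to under 420 bp (right panel, percent of circles) in control, 5 Gy x2 and 5 Gy x4 skin, with bars for the mean of 4 libraries, error bars for the SD and numbered points for single libraries. The irradiated libraries lie at 60.5% to 70.3% and the control libraries at 16.1% to 44.6%.

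The length profile of the pooled circles peaked at 369 bp in control and at 358 bp in both irradiated groups, with a second peak at 200 or 201 bp. Single control libraries peaked at 369, 358, 357 and 367 bp and irradiated libraries at 358 or 359 bp. Lengths repeated at a spacing of 11 bp, close to a turn of the DNA helix, in all 12 libraries, where spacings from 6 to 16 bp were searched. The pooled autocorrelation of the lengths at that spacing was 0.522 in control, 0.763 in 5 Gy x2 and 0.774 in 5 Gy x4. With 2926 circles drawn from each library, it was 0.179 ± 0.0829 in control (SD, n = 4), 0.356 ± 0.0593 in 5 Gy x2 and 0.415 ± 0.0211 in 5 Gy x4, with an exact p of 0.0286 for each dose against control. These draws did not match the share of 330 to under 420 bp circles. When the circles drawn were also equal in number in each length class (2285 per library), it was 0.118 ± 0.0381 in control, 0.184 ± 0.0291 in 5 Gy x2 (exact p = 0.0571, n = 4) and 0.239 ± 0.0177 in 5 Gy x4 (exact p = 0.0286). Between the doses it was 0.0553 higher in 5 Gy x4 (exact p = 0.0286), and 0.0582 higher in the draws not matched by class (exact p = 0.143). The median length was 336.75 ± 20.6 bp in control, 363.75 ± 2.22 bp in 5 Gy x2 and 361.25 ± 1.5 bp in 5 Gy x4, a difference of 27.0 and 24.5 bp (exact p = 0.0286 each, adjusted p = 0.0857, n = 4). These differences were 17.1 and 13.6 bp among circles with at least 5 supporting reads (exact p = 0.400 and 0.429) and 17.1 and 14.6 bp without control replicate 4. Without any 1 irradiated library the exact p was 0.0857, with the groups still apart. The share under 1000 bp was 94.3% ± 2.07 in control, 97.8% ± 1.06 in 5 Gy x2 and 98.7% ± 0.176 in 5 Gy x4 (exact p = 0.0286 each, adjusted p = 0.0857). The 5 Gy x4 and 5 Gy x2 libraries differed by -2.5 bp in median length (exact p = 0.200) and by 0.870 percentage points in that share (exact p = 0.229). Without 5 Gy x2 replicate 3 the latter difference was 1.25 percentage points (exact p = 0.0286).

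**Figure D2:**
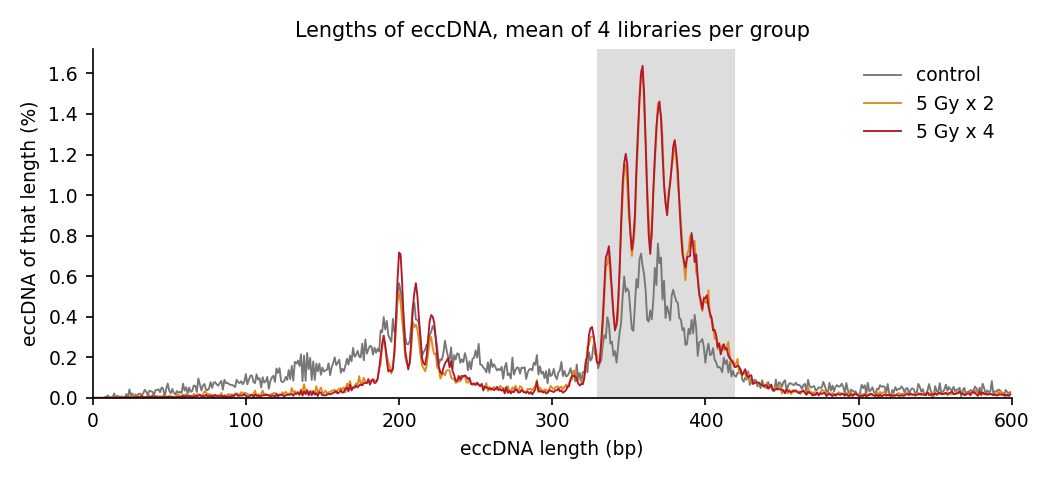
Length profile of the listed eccDNA, with length in bp on the horizontal axis and percent of circles on the vertical axis, as the mean of 4 libraries for control, 5 Gy x2 and 5 Gy x4. The grey band marks 330 to under 420 bp, which holds 32.2% of control, 66.5% of 5 Gy x2 and 67.2% of 5 Gy x4 circles.

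**Figure D3:**
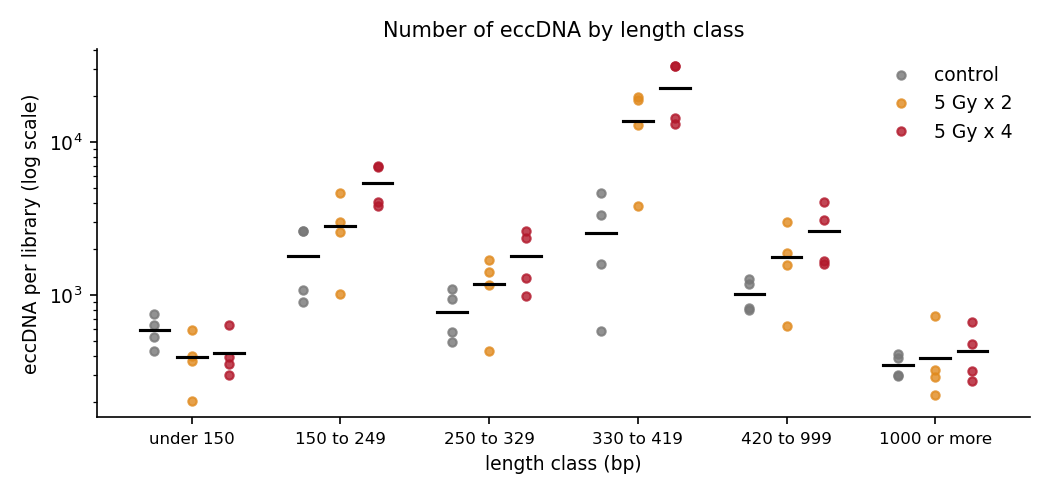
Number of eccDNA per library on a log axis in 6 length classes, with points for the libraries of each group and a short bar for the mean of 4. In 5 Gy x4 the class of 330 to under 420 bp is 8.93-fold the control number and the class of 1000 bp or more 1.24-fold.

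Relative to genes, exonic circles took a larger part of the irradiated libraries and intronic circles a smaller part. Exonic circles were 3.41% ± 0.701 of control circles (SD, n = 4), 4.53% ± 0.468 in 5 Gy x2 and 4.83% ± 0.256 in 5 Gy x4. Intronic circles were 33.8% ± 1.05, 31.9% ± 0.675 and 32.2% ± 0.361. Each of these had an exact p of 0.0286 against control and an adjusted p of 0.110. The genic share as a whole was 37.2% ± 0.576 in control, 36.5% ± 1.13 in 5 Gy x2 (exact p = 0.314) and 37.0% ± 0.517 in 5 Gy x4 (exact p = 0.543), within the spread between libraries. Among circles of 1000 bp or more the direction turned, with a genic share 2.52 percentage points higher in 5 Gy x2 (exact p = 0.0857, n = 4) and 4.96 higher in 5 Gy x4 (exact p = 0.0286). Among circles of 330 to under 420 bp the exonic share was 3.95% ± 0.737 in control and 5.14% ± 0.172 in 5 Gy x4 (exact p = 0.0286, n = 4), and among other lengths 3.11% ± 0.611 and 4.20% ± 0.419 (exact p = 0.0286). The exonic share in 5 Gy x2 was 4.77% ± 0.356 (exact p = 0.0857) and 4.05% ± 0.763 (exact p = 0.143) in these 2 sets.

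Chromosome 12 differed most between control and irradiated skin in relative terms. It held 3.73% ± 0.744 of control circles, 2.00% ± 0.181 of 5 Gy x2 circles and 1.84% ± 0.0822 of 5 Gy x4 circles (SD, n = 4, exact p = 0.0286 each). Per Mb, chromosome 12 carried 4.70 ± 1.66 circles in control against 2.58 ± 1.27 on chromosome 1, and 11.7 ± 5.14 against 11.8 ± 4.95 in 5 Gy x4. Chromosomes 19, 20 and X also held a smaller share in both irradiated groups and chromosomes 4 and 11 a larger one. Chromosome 20 in 5 Gy x4 went from 2.71% ± 0.216 to 2.17% ± 0.0887 and chromosome 4 from 5.98% ± 0.645 to 6.94% ± 0.138 (exact p = 0.0286 each, n = 4). By exact permutation tests, 0 of 22 chromosomes passed after adjustment in any comparison, with 6 (5 Gy x2), 8 (5 Gy x4) and 1 (between the doses) at an exact p of 0.0286. The smallest adjusted p was 0.105 for 5 Gy x2 and 0.0786 for 5 Gy x4.

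In windows of 10 Mb, gene-poor regions on average gained and gene-dense regions on average lost a share of the circles in irradiated skin. In 5 Gy x4 against control, 81 of 286 windows passed an adjusted p of 0.05 with edgeR, 29 higher and 52 lower. With library size alone 96 passed, 49 higher and 47 lower, among them 76 of the 81 in the same direction, so the excess of lower over higher windows was not kept. The largest rise with groups apart was on chromosome 5 from 80000001 to 90000000, where the control mean was 12.8 ± 9.91 circles and the 5 Gy x4 mean 128 ± 49.8 (log2 fold change 1.01, SE 0.21, adjusted p = 1.41e-05, n = 4). Windows on chromosome 11 from 20000001, chromosome 8 from 80000001 and chromosome 6 from 60000001 rose by 0.87 to 0.93 on the log2 scale. The largest falls were in the last windows of chromosome 12. The window from 50000001 fell by 1.45 (SE 0.23, adjusted p = 6.41e-09) and that from 40000001 fell by 1.27 (SE 0.15, adjusted p = 6.11e-15) on the log2 scale. Windows on chromosome 3 from 160000001 and chromosome 6 from 130000001 fell by 1.14 each. These changes are relative to all windows of a library, and the number of circles in each of these falling windows was larger in 5 Gy x4 than in control (45.8 ± 27.0 against 24.8 ± 11 in the window from 50000001 of chromosome 12).

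In 5 Gy x2 against control, 72 windows passed, 28 higher and 44 lower, and with library size alone 84, 45 higher and 39 lower, among them 67 of the 72 in the same direction. The windows with the largest rises lay on chromosome 14 from 50000001 (log2 fold change 1.04, SE 0.25, adjusted p = 5.27e-04, n = 4), chromosome 5 from 80000001 (0.98), chromosome 1 from 110000001 (0.92) and chromosome 11 from 10000001 (0.90). The largest falls were again on chromosome 12 from 50000001 (fell by 1.17, SE 0.23, adjusted p = 1.05e-05) and 40000001 (fell by 1.13), followed by chromosome 9 from 10000001 (fell by 1.10) and chromosome 8 from 120000001 (fell by 1.08). All 6 windows of chromosome 12 were lower at both doses. Between the doses 0 windows passed with edgeR, with 9 at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom. The 2 contrasts share the control libraries, and their log2 fold changes had a correlation of 0.968 across windows, where simulated counts with no change gave 0.780 through the shared controls. With the controls divided between the contrasts, the correlation was 0.729 to 0.760 over 6 ways of dividing them. With all controls in both contrasts, 43 windows fell and 24 rose in both, where independent calls would give 8.0 and 2.84 and the simulated counts gave 0. Windows are not independent replicates.

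The falling windows held a median of 62.5 genes with a listed circle at both doses, and the rising windows 25 (5 Gy x2) and 24 (5 Gy x4). Single windows departed from this. In 5 Gy x4 the rising window of chromosome 8 from 80000001 held 49, where windows not called had a median of 45. The falling window of chromosome 12 from 50000001 held 27, but circles on that chromosome ended at 52.7 Mb, so it is not a full window. The 72 of 291 windows with most such genes (at least 69) held 32.7% ± 2.77 of control circles, 27.8% ± 1.09 of 5 Gy x2 circles and 27.3% ± 0.558 of 5 Gy x4 circles (SD, n = 4, exact p = 0.0286 each). With only circles of 330 to under 420 bp, 1 window passed in each contrast with control, against 32 (5 Gy x2) and 81 (5 Gy x4) with circles of other lengths. Control libraries held 2529 ± 1800 circles of 330 to under 420 bp, and replicate 4 only 579. With so few per window, the missing calls do not show that the shift was absent in this class. Within 330 to under 420 bp the gene-dense share was 30.1% ± 3.88 in control, 26.8% ± 1.03 in 5 Gy x2 (exact p = 0.143, n = 4) and 26.7% ± 0.501 in 5 Gy x4 (exact p = 0.0571). At a common mix of 20 length bins it was 31.8% ± 3.04 in control, 28.3% ± 0.967 in 5 Gy x2 and 27.7% ± 0.587 in 5 Gy x4 (exact p = 0.0286 each, n = 4). Control replicate 4 carried much of these 2 differences. Without it, that at the common mix went from -3.57 to -2.10 percentage points in 5 Gy x2 (exact p = 0.0571) and from -4.10 to -2.63 in 5 Gy x4 (exact p = 0.0286). Within 330 to under 420 bp it went from -3.36 to -1.55 (exact p = 0.229) and from -3.39 to -1.58 (exact p = 0.0571). Windows were added after the gene counts were seen to be sparse.

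**Figure D4:**
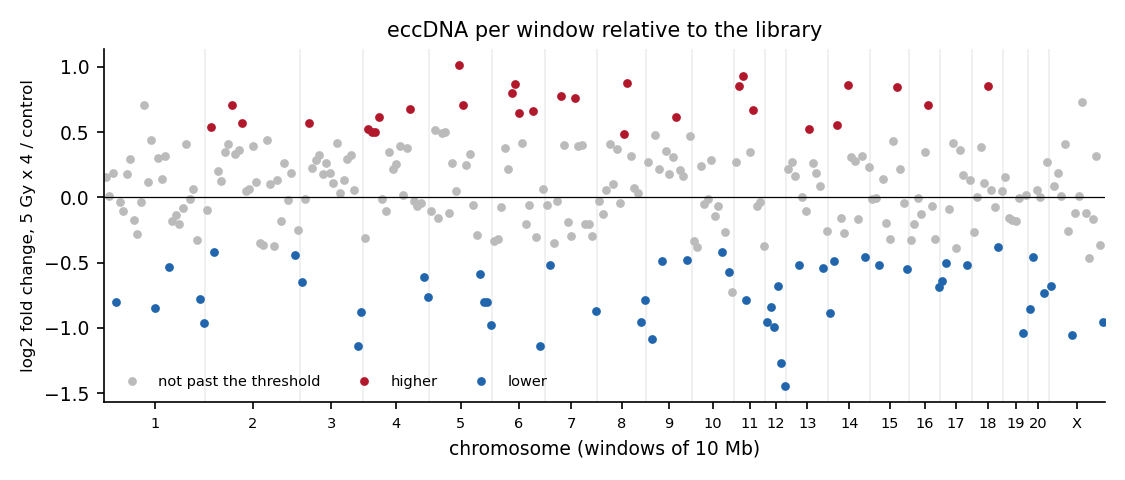
Log2 fold change in the number of eccDNA per 10 Mb window, 5 Gy x4 over control, by position along the chromosomes, relative to all windows. Red points are the 29 windows past an adjusted p of 0.05 and higher, blue points the 52 lower, grey points the rest; all 6 windows of chromosome 12 are lower.

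Few genes carried enough circles to be tested one by one: 15 of 14890. In 5 Gy x4 against control, edgeR put 9 of the 15 past an adjusted p of 0.05, 4 higher and 5 lower relative to the other tested genes. The balance depended on the settings. With a filter of at least 10 circles in 4 libraries 11 of 31 genes passed, 9 higher and 2 lower. With library size alone 8 of 15 passed, 2 higher and 6 lower. The rising genes with groups apart were Luzp2 (ENSRNOG00000021507, chromosome 1, circles from 111854059 to 113527175), with 1.00 ± 0.816 circles per control library and 17.3 ± 6.29 per 5 Gy x4 library (SD, n = 4; log2 fold change 2.14, SE 0.60, adjusted p = 0.00305), Astn2 (ENSRNOG00000060105, chromosome 5; 1.71, SE 0.52, adjusted p = 0.00462) and Nrxn3 (ENSRNOG00000047574, chromosome 6; 1.28, SE 0.50, adjusted p = 0.0322). Astn2 and Nrxn3 are long genes with roles in neurons, Nrxn3 encoding a synaptic adhesion protein. The falling genes with groups apart were Apoo (ENSRNOG00000046918, chromosome X, circles from 63524652 to 63615963), Ighm (ENSRNOG00000034190, chromosome 6) and St6galnac3 (ENSRNOG00000056894, chromosome 2). Apoo, which encodes a protein of the mitochondrial inner membrane, fell by 2.01 (SE 0.41, adjusted p = 7.40e-05) on the log2 scale while its number of circles was 16.3 ± 7.54 in control and 14.5 ± 2.08 in 5 Gy x4. Its 173 circles over all libraries lay on 102 entries, against 117 on 113 for Luzp2, so more of them recurred. A recurrent circle counts once per library, so this fall in share does not show a loss of Apoo circles. Ighm, the immunoglobulin mu heavy chain locus, fell by 1.62 (SE 0.38, adjusted p = 4.21e-04) and St6galnac3, a sialyltransferase gene, fell by 1.31 (SE 0.39, adjusted p = 0.00462). Pard3b rose and Rbms3 and Galnt17 fell past the threshold with overlapping libraries. With 1 library left out, Rbms3 passed in 0 of 8 fits (adjusted p = 0.0560 to 0.481) and Galnt17 only without control replicate 4 (otherwise 0.210 to 0.366), and Pard3b had 0.101 without control replicate 2 and 0.0827 without control replicate 4. Groups were compared on shares, and chance alone puts 1 of 35 splits of 8 libraries fully apart. Luzp2, Apoo and Astn2 passed with any 1 library left out where they could be tested. Without control replicate 2 the count was 5, and Ighm, Nrxn3 and St6galnac3 had adjusted p values of 0.0524, 0.0524 and 0.101. Ighm also had 0.0538 without 5 Gy x4 replicate 3, and St6galnac3 0.283 without control replicate 3 and 0.0538 to 0.0798 without any 1 of the 5 Gy x4 libraries. On simulated counts 2 of 8 unchanged genes were called, but 12 of the 22 genes tested there were changed 4-fold. The rate of false calls in the real fit is thus unknown.

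Of the 15 genes, 6 passed in 5 Gy x2 against control, 2 higher and 4 lower. With the filter of at least 10 circles 9 of 31 passed (6 higher, 3 lower), and with library size alone 5 of 15 (1 higher, 4 lower). Luzp2 rose by 1.97 on the log2 scale (SE 0.63, adjusted p = 0.00896, n = 4), from 1.00 ± 0.816 to 11 ± 5.77 circles, and was the only gene of the 6 with groups apart. Pard3b rose and Apoo, Ighm, Rbms3 and Galnt17 fell with overlapping libraries. With 1 library left out, Luzp2 passed in 8 of 8 fits and Apoo in all but that without 5 Gy x2 replicate 2 (adjusted p = 0.116). Galnt17 passed only without control replicate 4 or 5 Gy x2 replicate 3 (otherwise 0.120 to 0.292). Ighm did not pass without control replicates 2 or 4 or 5 Gy x2 replicates 1, 2 or 3 (0.0523 to 0.132), Rbms3 without control replicates 2 or 3 or 5 Gy x2 replicates 2 or 4 (0.0553 to 0.294), and Pard3b without control replicates 2 or 4 (0.0668 and 0.0857). The count was 10 without 5 Gy x2 replicate 1 and 14 without replicate 4. Between the doses, 0 of 15 genes passed with edgeR, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0. The lowest p values in that comparison, none past the threshold, belonged to Astn2 (log2 fold change 0.67, SE 0.32, adjusted p = 0.6), then to St6galnac3, Rbms3, Nrxn3, Galnt17, Apoo, Dmd, Gpc6, Luzp2 and an unnamed gene on chromosome 4 (ENSRNOG00000006617), with log2 fold changes from -0.49 to 0.44. The gene with most circles was Mycbp2 on chromosome 15 (529 over all libraries), whose circles lay from 87507985 to 93807934. Numbers were not divided by the length of a gene. Chromosome 15 held 9589 circles over 111 Mb in all libraries, so the number in this long span does not show a hotspot. Mycbp2 held 14.8 ± 9.74 circles per control library and 69.8 ± 25.9 per 5 Gy x4 library. Its edgeR log2 fold change was 0.32 relative to the other genes (SE 0.27, adjusted p = 0.290). The calls rest on the filter: without it, TMM gave 0 genes in 5 Gy x2 (593 at an unadjusted p under 0.05) and 4 in 5 Gy x4, all higher, and DESeq2 with the filter gave 0 (6 at an unadjusted p under 0.05) and 4. When all 14890 genes were tested with library size alone, 4 genes fell in 5 Gy x2 (Apoo, AABR07040864.1, Rhox2 and Eya2) and 9 in 5 Gy x4 (these, Pde6h, Ighm, AABR07058884.1, AC141959.1 and Lor), and 0 rose. Without the filter the direction of the calls differed with the scaling. Unfiltered TMM factors ran against library size, from 2.87 in control replicate 4 (1421 genic circles) to 0.532 in 5 Gy x4 replicate 3 (17839), so the TMM calls are uncertain.

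Genes that keratinocytes express held a smaller share of genic circles in irradiated skin, and with all libraries the list did not pass after adjustment by the exact test of shares or by camera. The 31 genes of the epidermal keratinocyte list (24 with a circle) held 0.286% ± 0.0584 of the genic circles in control, 0.141% ± 0.0377 in 5 Gy x2 and 0.126% ± 0.0104 in 5 Gy x4 (SD, n = 4, exact p = 0.0286 each, adjusted p = 0.214 over 15 lists), with 7.75 ± 3.77 circles per control library and 16.5 ± 8.19 per 5 Gy x4 library. Camera placed the list lower in 5 Gy x4 (adjusted p = 0.127; adjusted p = 0.256 with an estimated correlation) and passed it without control replicate 1. Fry, which tests the members for a change of their own and not against the other genes, gave an adjusted p of 0.0426 in 5 Gy x4. Of its 24 members 1 passed over all genes, Lor, and 2 adjusted over the list alone, Lor and Krt14. Lor, which encodes the cornified envelope protein loricrin, had 1.5 ± 0.577 circles per control library and 0 in the 5 Gy x4 libraries, and Krt14, a basal cell keratin, 1.5 ± 1.00 and 0.750 ± 0.5 (adjusted p = 0.0283 over the list alone). Krt5 had 1.5 ± 1.29 circles in control and 1.75 ± 1.5 in 5 Gy x4 (adjusted p = 0.212 over the list alone). The median fitted log2 change of the list was 0.15 and its mean -0.11, which differ in sign. In 5 Gy x2, 0 members passed over all genes or over the list alone, 3 had an unadjusted p under 0.05 and the camera adjusted p was 0.209, with a median of 0.08 and a mean just under 0.

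Among the other lists, 0 of the 14 passed in 5 Gy x4 against control with camera and library size alone, and 0 members passed over all genes or adjusted over the list alone. The DNA damage and p53 response list (11 members with a circle, 36 circles over all libraries) had an adjusted p of 0.571, and Mdm2, the ubiquitin ligase that restrains p53, had 0 circles in control and 0.250 ± 0.5 in 5 Gy x4. The DNA repair list (31 members, 278 circles) had an adjusted p of 0.808, with 1 member, Msh3, at an unadjusted p under 0.05. Msh3 held a smaller share of genic circles in 5 Gy x4, although its number went from 1.75 ± 1.5 circles in control to 2.50 ± 0.577. The extracellular matrix and fibrosis list (31 members) had an adjusted p of 0.960, and its lowest p belonged to Col14a1, with 0 circles in control and 4.75 ± 2.87 in 5 Gy x4. Inflammation (0.960), immune cell (0.827), oxidative stress (0.960) and apoptosis (0.819) lists had the camera adjusted p values given in brackets, as did hair follicle and sebaceous gland (0.862), skeletal muscle (0.445), adipocyte (0.445), endothelium and pericyte (0.808), and Schwann cell and melanocyte (0.808) lists. The DNA repair, extracellular matrix and inflammation lists had medians and means above 0 and a lower direction by camera, which compares a list with the other genes. Of the 15 lists, 0 passed in 5 Gy x2 against control by that test, with 3 at an unadjusted camera p under 0.05: epidermal keratinocyte and adipocyte (lower) and long neuronal genes (higher), each with an adjusted p of 0.209. By fry, 0 of the 15 lists passed in 5 Gy x2. Without control replicate 2, camera passed 2 lists in 5 Gy x2, adipocyte and long neuronal genes.

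Long neuronal genes held a larger share of genic circles in irradiated skin, and oncogenes a larger one in 5 Gy x4 than in 5 Gy x2, and whether either list passed after adjustment differed between tests. The long neuronal genes (15 members with a circle, 956 circles) held 0.745% ± 0.312 of genic circles in control, 1.08% ± 0.107 in 5 Gy x2 (exact p = 0.0571, n = 4) and 1.04% ± 0.105 in 5 Gy x4 (exact p = 0.0286, adjusted p = 0.214), with a camera adjusted p of 0.445 in 5 Gy x4. With TMM in place of library size alone, camera passed the list at both doses (adjusted p = 3.04e-09 in 5 Gy x2 and 4.49e-14 in 5 Gy x4), so its call depends on the scaling. The unfiltered TMM factors were 1.22 to 2.87 in control libraries, with 1421 to 3906 genic circles. They were 0.532 to 0.788 in 5 Gy x4 libraries, with 7527 to 17839 genic circles. These factors ran against library size on sparse counts, so calls that rest on unfiltered TMM are uncertain. Dlg2, a synaptic scaffold gene, had 0.5 ± 0.577 circles per control library and 10.5 ± 4.65 per 5 Gy x4 library (adjusted p = 0.181 over the list alone). The oncogene and growth factor receptor list (20 members, 205 circles) held 0.142% ± 0.0685 of genic circles in 5 Gy x2 and 0.244% ± 0.0343 in 5 Gy x4 (exact p = 0.0286, adjusted p = 0.429). Its camera adjusted p between the doses was 0.0540 (0.169 with an estimated correlation), the lowest of 15 lists, and against control 0.330 in 5 Gy x2 and 0.960 in 5 Gy x4. Between the doses the list passed by camera with TMM (adjusted p = 0.0231), and with library size alone when 5 Gy x2 replicate 2 or 5 Gy x4 replicate 1 was left out. Fry, which does not compare the list with the other genes, gave an adjusted p of 0.0278. Egfr had 0.750 ± 0.957 circles in 5 Gy x2 and 3.25 ± 2.06 in 5 Gy x4, and Cdk6, a cell cycle kinase gene, 1.25 ± 0.957 and 4.50 ± 3.11, neither past the threshold. In the filtered fit the long neuronal list alone could be tested, with 2 members and camera p values of 0.445, 0.410 and 0.660 in the 3 comparisons.

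The 10 circles found in all 12 libraries were the mitochondrial genome, 4 intronic and 5 intergenic circles. The mitochondrial circle had 1227 ± 760.1 supporting reads in control and 5350 ± 797 in 5 Gy x4 (4.36-fold, exact p = 0.0286, n = 4), and the supporting reads of the other 9 were not tested. Intergenic ones included chromosome 3 from 32684 to 33068 (385 bp; 265 ± 241 supporting reads in control and 280 ± 143 in 5 Gy x4, SD, n = 4) and chromosome 18 from 4696251 to 4696311 (61 bp; 306 ± 181 and 250 ± 83.4). Intronic circles recurred in Mipep on chromosome 15 (2560 bp; 110 ± 60.1 and 68.8 ± 28.9), Apoo on chromosome X (31295 bp; 42.8 ± 39.9 and 55.5 ± 69.8), Pkd2 on chromosome 14 (1500 bp; 72.8 ± 37.1 and 96.0 ± 61.0) and Laptm4b on chromosome 7 (464 bp; 56.8 ± 15.2 and 49.0 ± 21.8). The other intergenic ones lay on chromosome 10 from 67234383, chromosome 7 from 142066301 and chromosome 17 from 55374695. For 4 of the 10 the library counts sum to less than the annotation table gives: Apoo (529 of 1252 reads), Mipep (952 of 1695), Pkd2 (926 of 1111) and the chromosome 10 circle (1228 of 1354). Which is right is unknown, so these means are uncertain. Circles found in 8 or more libraries numbered 157 ± 9.02 per control library, 146 ± 7.70 in 5 Gy x2 (exact p = 0.114) and 152 ± 9.54 in 5 Gy x4 (exact p = 0.429). They were chosen by presence in these same libraries, so their number could differ little between groups. Circles found in 1 library went from 5256 ± 2974 in control to 31044 ± 13501 in 5 Gy x4 (5.91-fold, exact p = 0.0286).

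Control libraries shared more of their circles with each other than irradiated libraries did. By an overlap of 50% of both circles, the mean within a group was 10.9% in control, 2.81% in 5 Gy x2 and 2.05% in 5 Gy x4, against 4.08% between groups. Over all groups the mean within groups was 5.24%, 1.16 percentage points above that between groups (permutation p = 1.30e-04, 12 libraries). That p is an estimate from random resamples and is about the smallest that 12 libraries in 3 groups of 4 allow. Within both irradiated groups the mean was below that between groups. The values and the permutation were not adjusted for the number of circles in a library, which differed between groups.

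The number of larger circles listed as ecDNA differed by less than the spread between libraries, with 37.5 ± 10.1 per control library, 31.5 ± 16.1 in 5 Gy x2 (exact p = 0.571, n = 4) and 31.5 ± 8.02 in 5 Gy x4 (exact p = 0.429). Divided by supporting reads, the number was 0.627-fold the control value in 5 Gy x2 (exact p = 0.457) and 0.318-fold in 5 Gy x4 (exact p = 0.0286, n = 4). The 157 entries had a median length of 920636 bp and a minimum of 100639 bp, 137 overlapped exons, 88 were found in 1 library and 25 rested on 1 supporting read. All 157 carried the label lconf. The 5 longest lay on chromosome 3 from 58410415 to 67790615 (9380201 bp, 6 supporting reads), chromosome 19 from 52860244 to 61927631 (59 reads), chromosome 1 from 173448836 to 182391651 (1 read), chromosome 2 from 84233542 to 92908127 (6 reads) and chromosome 9 from 49868205 to 57902916 (1 read). The chromosome 3 entry spans the Hoxd cluster and was found in 1 library of 5 Gy x4. Of the 5 best supported, 4 overlapped each other between genes on chromosome 1 from 180492395 to 182071383, led by an entry of 859560 bp found in all 12 libraries. Its library counts (4756 of the 42981 reads of the annotation table) were 954 ± 1192 in control, 143 ± 81.3 in 5 Gy x2 and 91.8 ± 66.4 in 5 Gy x4 (SD, n = 4). Control replicates 1 to 4 had 56, 20, 1198 and 2542 of these reads. Another of the 4 overlapping entries had the same coordinates as this one, from 180493000 to 181352559. It also had the same count in some libraries, such as 1198 in control replicate 3. Entries may thus repeat the same circle, and the numbers of ecDNA per library may count it more than once. The fifth best supported entry lay on chromosome 2 from 159003948 to 161018557.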

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

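The screen covered 84 groups of 4 libraries, of which chance alone would single out about 1 in 20, and the tests of this part were chosen after the results were seen, apart from the planned comparison of the share under 1000 bp, whose use here was chosen afterwards. In 4 libraries 5 values lay far from those of the other 3 of the group. Replicate 4 of 5 Gy x2 held 60.5% of its circles at 330 to under 420 bp, the others 68.1% to 68.6%. Control replicate 4 had an exonic share of 2.36% (others 3.73% to 3.81%) and 47.1% of circles with the label hconf (others 36.9% to 38.3%). Replicate 2 of 5 Gy x2 had 30.3% with the label conf (others 6.63% to 9.11%). Control replicate 1 had 97.2 circles per 1000-fold mitochondrial depth (others 448.96 to 510).

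The larger number of eccDNA in 5 Gy x4 may reflect deeper sampling, a higher recovery of circles or the irradiation itself. At equal supporting reads the fold was still 2.85 (exact p = 0.0286, n = 4), which argues against supporting reads as the whole cause, although the number divided by supporting reads was 1.85-fold (exact p = 0.229) and part of the fold may come from them. A recovery that raised the listed number at every length by the same factor would leave the share under 1000 bp where it was. That share was 4.33 percentage points higher (exact p = 0.0286). A circle counts once however often it is recovered, so recurrent circles cannot gain in number as rare ones do. The share can thus change with a recovery alike at every length, and the test cannot decide. That recovery stays open, as does total sequencing depth. A recovery that depends on length was not tested and stays open too. The number per mitochondrial depth was 0.776-fold the control value (0.584-fold in 5 Gy x2). Irradiation and time of sampling cannot be separated by these groups.

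The larger share of 330 to under 420 bp circles may come from weakly supported circles or from circles formed on nucleosome-bound DNA. Among circles with at least 5 supporting reads the share was 34.5 percentage points higher in 5 Gy x4 than in control (exact p = 0.0286, n = 4), which argues against few supporting reads as the cause. That does not settle the quality of the calls. Circles with the undefined label lconf were 32.9% of control and 62.6% of 5 Gy x4 circles. With equal numbers of circles drawn from each length class, the autocorrelation at 11 bp was 0.121 higher in 5 Gy x4 (exact p = 0.0286). In 5 Gy x2 the autocorrelation was 0.0655 higher (exact p = 0.0571), and lengths can still differ within a class. These draws hold the share of each class equal, so they cannot decide whether the larger share has a nucleosomal origin. Length-dependent recovery was not tested and stays open.

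The smaller share of circles in gene-dense windows may follow from the mix of lengths or from dilution of recurrent circles. At a common mix of 20 length bins the difference was -4.10 percentage points in 5 Gy x4 against control, and among circles found in 1 library -5.07 (exact p = 0.0286 each, n = 4), which argues against either as the whole cause. Both rest in part on control replicate 4: without it they were -2.63 and -3.07 (exact p = 0.0286 each). Without any 1 of the 5 Gy x4 libraries the exact p was 0.0857 and 0.0571, with the groups still apart. With all circles as listed it was -5.42, so the mix of lengths may account for a part. Within 330 to under 420 bp the difference was -3.39 (exact p = 0.0571, and -1.58 without control replicate 4). Only 1 window passed there, on few control circles per window. Among circles of 1000 bp or more the difference was -0.0215 (exact p = 1), so it was not seen at every length. A bias by GC content was not tested and stays open, and so do irradiation and time of sampling.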

How the results depend on the processing

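Alternatives on hconf circles, circles found in 1 library, length classes, numbers at equal supporting reads, every call counted, lengths of single calls, mitochondrial depth, supporting reads as values of genes, 2 kb flanks, unfiltered genes with library size alone, ecDNA of at least 2 supporting reads, unfiltered gene lists, leaving out libraries for measures added later, and all on 10 Mb windows and the 330 to under 420 bp share were chosen after the data were seen. Library measures are called here at an unadjusted exact p threshold of 0.05. None of the 15 planned or 69 added tests passed after adjustment. Of 458 values of comparisons under an alternative, 387 kept their side of the threshold (counts: stayed within 1.5 times), some of those not past it with a turned direction, such as the number of eccDNA in 5 Gy x2 divided by mitochondrial depth (0.584-fold) and the 5 Gy x2 genic share of circles of 1000 bp or more (2.52 points). Of 309 values of single genes and windows 188 kept direction and side; the cause of the other changes was not tested unless given. The number of eccDNA in 5 Gy x4 over control was 1.85-fold divided by supporting reads (exact p = 0.229) and 0.776-fold, reversed, divided by mitochondrial depth. With 1 library left out it was 4.05 to 5.59-fold (exact p = 0.0286 to 0.0857), the call ending without any 1 control library (4.26, 5.31, 5.59 and 4.05 without replicates 1 to 4). In 5 Gy x2 it was 2.48 to 3.55-fold, the highest without 5 Gy x2 replicate 4 (exact p = 0.0286). The difference in median length was 17.1 bp (5 Gy x2) and 13.6 bp (5 Gy x4) with at least 5 supporting reads (exact p = 0.400 and 0.429), 39.4 bp in 5 Gy x4 for hconf circles (exact p = 0.171), and 17.1 to 31.8 bp and 14.6 to 29.2 bp with 1 library left out, the call ending without any 1 irradiated library (exact p = 0.0857). The difference in share under 1000 bp in 5 Gy x2 was 4.85 points with at least 5 supporting reads (exact p = 0.114), 1.92 for hconf circles (exact p = 0.0857) and 2.55 to 4.09 with 1 library left out, the call ending without any 1 5 Gy x2 library or control replicate 4 (2.55); in 5 Gy x4 it was 3.42 to 4.96, the call ending without any 1 5 Gy x4 library (exact p = 0.0571), and between the doses 0.432 to 1.25, the highest without 5 Gy x2 replicate 3 (exact p = 0.0286). With replicate number as a block the values were 4.71-fold for number (5 Gy x4), 27.0 and 24.5 bp for median length, 3.46 and 4.33 points for the share under 1000 bp and 34.2 and 34.95 points for the share of 330 to under 420 bp; the smallest exact p is then 0.125, so these calls end by construction. Only 3 of 12 library pairs with the same replicate number correlated above 0.1 over 286 windows (-0.114 to 0.407), so the numbers were not taken to pair samples. The genic share of circles of 1000 bp or more was 4.96 points higher in 5 Gy x4 (exact p = 0.0286), a reversed direction. The number of ecDNA in 5 Gy x4 over control, divided by supporting reads, was 0.318-fold (exact p = 0.0286). Per Mb 22 chromosomes passed in 5 Gy x4, but these values are not divided by library totals and follow the larger eccDNA number. Genes past the threshold in 5 Gy x2 were 0 without a filter (593 at an unadjusted p under 0.05), 1 without the 10 genes with most circles, 0 with DESeq2 (6 unadjusted; limma-voom 4), 0 in a fit of only the 2 groups (2 genes tested), 2 with supporting reads, 0 with 330 to under 420 bp circles (2 tested), 1 with circles found in 1 library, and 4 to 14 with 1 library left out (10 without 5 Gy x2 replicate 1, 14 without replicate 4). In 5 Gy x4 these counts were 4, 1, 4 (limma-voom 6), 1, 0 (370 unadjusted), 0 and 1, and 5 to 12 with 1 library left out (5 without control replicate 2); between the doses supporting reads gave 1. Without a filter Galnt17 (0.18) and Rbms3 (0.25) had reversed log2 fold changes in 5 Gy x4. For lists, unfiltered TMM gave 1 in each comparison, fry 1 in 5 Gy x4 and 1 between the doses, and the replicate block 1 between the doses; with camera and library size alone 2 lists passed in 5 Gy x2 without control replicate 2 (adipocyte, long neuronal), 1 in 5 Gy x4 without control replicate 1 (keratinocyte) and 1 between the doses without 5 Gy x2 replicate 2 or 5 Gy x4 replicate 1 (oncogene). Windows past the threshold in 5 Gy x2 and 5 Gy x4 were 1 and 1 with 330 to under 420 bp circles, 32 and 81 with other lengths, 34 and 40 with circles found in 1 library, and 20 and 49 with hconf circles. With 1 library left out they were 56 to 76 and 63 to 87. With library size alone they were 84 (45 higher, 39 lower) and 96 (49 higher, 47 lower). Measures added later were also computed without each library. In 5 Gy x4 the number of 330 to under 420 bp circles was then 7.10 to 12.4-fold, its call ending without any 1 control library (exact p = 0.0571), and the difference in intronic share -2.03 to -1.21 points, its call ending without any 1 5 Gy x4 library (exact p = 0.0571). The exonic share was 1.07 to 1.55 points higher in 5 Gy x4 (exact p = 0.0286) and 0.771 to 1.35 in 5 Gy x2, its call ending without any 1 control library (exact p = 0.0571). The difference in gene-dense share was -6.18 to -4.10 points in 5 Gy x4, its call ending without 5 Gy x4 replicate 1 (exact p = 0.0571). Without a genome, no replicate block with GC content and length was run. Pseudocount and unit alternatives were not run, the values being counts.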

Other observations

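All tests of circle labels were chosen after the data were seen. Circles with the label lconf made up 32.9% ± 10.5 of control circles (SD, n = 4), 60.02% ± 8.97 in 5 Gy x2 and 62.6% ± 5.49 in 5 Gy x4 (exact p = 0.0286 each, adjusted p = 0.110), and circles with the label hconf 39.9% ± 4.87, 26.3% ± 2.25 and 27.2% ± 0.949 (exact p = 0.0286 each, adjusted p = 0.110). Circles in the 2 kb upstream of genes were 1.90% ± 0.205 in control and 1.67% ± 0.0755 in 5 Gy x4 (exact p = 0.0571, n = 4), and those in the 2 kb downstream 1.52% ± 0.147 and 1.53% ± 0.0770 (exact p = 0.943). Apoptosis genes held 0.0132% ± 0.0153 of genic circles in control and 0.0514% ± 0.0144 in 5 Gy x2 (exact p = 0.0286, adjusted p = 0.214, n = 4), resting on 0.5 and 4.25 circles per library.

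Other splits of the same 8 libraries, 35 per comparison with the real one, were run through the same fits. In 5 Gy x2 against control the real split gave 6 genes and the highest other 8, so that 2 splits gave as many and chance cannot be excluded. For 5 Gy x4 it gave 9 genes and the highest other 4, with 1 split as large, the real one. For 10 Mb windows the real split gave 72 (highest other 61) in 5 Gy x2 and 81 (highest other 0) in 5 Gy x4, with 1 split as large in each. Between the doses it gave 0 genes (highest other 1) and 0 windows (highest other 0), and for gene lists 0 in each comparison (highest other 1 in 5 Gy x2, 0 in 5 Gy x4 and 1 between the doses), so all 35 splits gave as many.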
